A study of Hydrangea macrophylla with 27 samples.

How the data were processed

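Whole stems of Hydrangea macrophylla 'Wudu' were sequenced in 27 libraries, 3 for each of 9 groups: before bending, and bent or unbent at 1, 3, 24 and 72 h. Per the labels, RNA was enriched for poly(A) transcripts and sequenced as paired reads of 150 bases on an Illumina NovaSeq instrument, and each library is a separate sample. The p-values therefore measure the spread between these samples, and bending was given on a single day. No genome was used. Values refer to 142016 assembled transcript clusters with a median length of 626 bases (301 to 15975). The assembler is not given in the sources used here.

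The deposited count table holds expected counts, which were computed with RSEM 1.2.28 per the submitters' processing notes. Of its values, 8.05% were not whole numbers, and all were rounded before the tests. The deposited annotation table holds FPKM values for the same clusters and libraries, with database matches. FPKM was used only as an alternative for named genes, as log2(FPKM + 0.1) and log2(FPKM + 1) in limma. A Swiss-Prot match was listed for 32636 clusters (23.0%) and a gene symbol for 29429. A name is the best match of a cluster, often from another plant, and fragments and paralogs of 1 gene may share reads. Total expected counts per library were 14.4 M to 23.1 M. No pair of libraries within a group was a duplicate, as the chi-square per degree of freedom was 4.68 to 20.7.

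Counts were analyzed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Clusters were kept by edgeR's filterByExpr on the 9 groups, which left 52918, and libraries were scaled by the trimmed mean of M-values (TMM). A robust quasi-likelihood model with 1 coefficient per group was fitted to all 27 libraries. The common biological coefficient of variation was 0.158 and the median prior degrees of freedom were 30.4. Bent and unbent stems were compared at each time, unbent stems at each time with those before bending, and F tests asked whether the bending effect differed between the 4 times and whether untreated stems changed over the 5 time points. Adjusted p-values are Benjamini-Hochberg values within each comparison, with a threshold of 0.05 and no minimum fold. In the text, CPM values (counts scaled to library size) are TMM-scaled, ± after a log2 fold change is its standard error, and ± after a mean is the standard deviation of 3 libraries. Principal components were computed from log2 CPM of the 2000 most variable clusters. Shares of counts were computed in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.

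Genes were named by a rule fixed before the data were examined. For each comparison of bent and unbent stems it took the 12 largest rises and 12 largest falls among clusters with a Swiss-Prot match. Their adjusted p was under 0.05, the higher group had at least 10 CPM, and the 3 bent and 3 unbent libraries did not overlap. Of the clusters within these limits, 607 of 821 had such a match at 1 h and 1673 of 2068 at 3 h. Up to 4 members of each gene list with an adjusted p under 0.05 were also taken, by smallest p. The rule gave 158 clusters, of which the report names a part. Genes named for unbent stems against before bending fall outside this rule.

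The 22 gene lists were calcium and touch, cell wall loosening, lignin and phenylpropanoid, jasmonate, ethylene, gibberellin, auxin, abscisic acid and drought, early response transcription factors, reactive oxygen, heat shock, organelle-encoded, circadian clock, photosynthesis, xylem markers, phloem markers, meristem and cell cycle, epidermis, Hydrangea ringspot virus, thrips, human and ribosomal RNA. The list families were fixed before the data were examined, while the patterns that search the annotation for their members were written after the annotation had been seen. The organelle and phloem patterns were corrected after list results had been seen, which removed COBRA proteins, cytosolic ribosomal proteins, psbW, ycf20, ycf23, ycf24 and PP2A phosphatases. The reactive oxygen and heat shock lists hold a few best matches from animals or fungi. Lists were tested with fry and with camera at a preset correlation of 0.01 or an estimated one, adjusted over the lists and times of bent against unbent stems and, separately, of unbent stems against before bending. Sets of clusters that passed at 1 h were followed to the later times with fry. Gene ontology processes were tested with Fisher's exact test.

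The alternatives were other size factors, no or a stricter filter on low counts (1 CPM in 3 libraries and a total of 100), DESeq2, limma-voom, a fit of only the groups compared, the replicate number as a block, a minimum 2-fold change, and each replicate left out in turn. Those without clusters of other organisms and rRNA, without 3 libraries rich in rRNA and without 2 libraries rich in thrips matches were chosen after the data had been seen.

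The scripts were tested on simulated data with the real means and library sizes, in which 100 clusters were changed by 2-fold and 100 by 4-fold. EdgeR recovered 58% and 89% of them, DESeq2 61% and 91%, and limma-voom 55% and 83%, and 0 came back in the wrong direction. Unchanged clusters made up 8.13% of edgeR's calls, 13.1% of DESeq2's and 8.61% of limma-voom's. A simulated comparison with no change gave 0, 3 and 0 calls. Among 200 unchanged sets, 3.5% had p under 0.05 in fry, 2% in camera with the preset and 2.5% with the estimated correlation. The simulated clusters were drawn independently of each other, so these shares do not cover lists whose members vary together. At this depth and with 3 libraries per group, a 2-fold change was called in 58% of the simulated clusters, so a cluster that did not pass is not shown to be unchanged. Isoform usage and sequence variants were not analyzed here.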

Results

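Gene expression was measured by poly(A) RNA sequencing in whole stems of Hydrangea macrophylla 'Wudu', an ornamental shrub grown here as potted micro-cuttings in a growth chamber with 16 h of light per day. The question of the series was how stems respond over time to mechanical stimulation. On a single morning, the treated plants were pushed over 12 times by a moving plastic curtain, which bent the stems to 30° from the vertical for some 30 s. Stems were collected 15 min before the treatment, and bent and unbent stems were collected 1, 3, 24 and 72 h after it. The sources do not state whether these hours count from the start or the end of the 12 bendings. These 9 groups held 3 libraries each, 27 in all. Total expected counts per library lay between 14.4 M and 23.1 M, with a median of 17.2 M, over 142016 assembled clusters, of which 52918 passed the filter on low counts. Genes are named by the best Swiss-Prot match of a cluster. Clusters that carry the same name can be paralogs or fragments of 1 transcript and may share reads, so the cluster identifier is given where a name occurs more than once.

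Harvest time set the largest differences between the libraries. On the first principal component, which held 40.2% of the variance, bent stems of 1 h scored 76.0 to 94.9 and unbent stems of 1 h scored 54.1 to 61.6, while all libraries of 24 and 72 h lay between -40.3 and -33.6. The second component held 11.9% and set apart the libraries of 3 h, with scores of 48.0 to 51.6 in bent and 27.0 to 38.0 in unbent stems. Ribosomal RNA (rRNA) took 4.70% ± 1.97 (SD, n = 3) of the counts in bent stems at 1 h against 2.97% ± 0.267 in unbent stems, 4.21% ± 1.32 against 3.42% ± 0.551 at 3 h, and 5.32% ± 2.79 before bending. Replicate 2 held the highest rRNA share in the groups before bending, bent at 1 h, and both bent and unbent at 3 h. Clusters that matched Hydrangea ringspot virus, a plant virus, took 4.21% ± 1.34 of the counts over the 27 libraries, with 2.79% ± 0.518 in bent and 4.52% ± 1.14 in unbent stems at 3 h. Clusters that matched thrips, which are plant-feeding insects, averaged 0.00924% ± 0.0168 of the counts, and were highest in replicate 3 before bending and replicate 2 of the bent stems at 24 h.

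At 1 h after bending, genes that act on the cell wall were among those that changed, in both directions. XTH22 (Cluster-9242.33400), a xyloglucan endotransglucosylase/hydrolase whose Arabidopsis counterpart is known as the touch-induced gene TCH4, rose from 30.8 ± 4.72 to 193 ± 85.7 CPM (mean ± SD, n = 3 per group), a log2 fold change of 2.64 ± 0.40 (SE). XTH23 (Cluster-9242.33401), of the same family, rose by 2.07 ± 0.27 on the log2 scale, and PHI-1 (Cluster-9242.44628), of a family tied to cell expansion, rose from 147 ± 17.3 to 753 ± 361 CPM. The expansins EXPA8, EXPB3, EXPB16 and EXPA4, which loosen walls, had log2 fold changes of -1.44 ± 0.25, -1.08 ± 0.11, -0.87 ± 0.13 and -0.82 ± 0.12. KCS1 and KCS11 (Cluster-9242.82290), of a family that elongates fatty acids, as for wax, rose by 1.51 ± 0.20 and 1.86 ± 0.25. Among transcription factors, MYB73 (Cluster-9242.29886) rose from 27.9 ± 1.36 to 58.0 ± 2.81 CPM and MYB48 fell from 9.51 ± 1.16 to 3.80 ± 0.836 CPM, with adjusted p of 1.27e-09 and 3.07e-06 from edgeR.

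In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1021 clusters passed at 1 h, 590 of them higher and 431 lower in bent stems. A change of at least 2-fold was reached by 172 of the higher and 74 of the lower clusters. Of the 1021, 690 had a Swiss-Prot name. Limma-voom called 1040 clusters and split them differently, with 778 higher and 262 lower, or 74.8% higher against 57.8% in edgeR, and a fit of only the 6 libraries compared called 885, 68.8% of them higher. The count fell to 370 without replicate 1 of the bent stems, and to 500 and 535 without replicates 1 and 2 of the unbent stems. In that fit of 6 libraries, XTH22, XTH23 and PHI-1 kept log2 fold changes of 2.63, 2.07 and 2.35 but no longer passed.

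Of 109 measured clusters in the calcium and touch list, 11 rose and 0 fell at 1 h (16 and 1 when adjusted over the list alone). CIPK7, a protein kinase of calcium signalling, rose from 27.4 ± 1.38 to 45.6 ± 8.71 CPM, and the calmodulin-like CML23 rose from 1.05 ± 0.625 to 7.03 ± 5.24 CPM, a call that was lost at a log2 fold change of 1.91 without replicate 1 of the bent stems, at 2.68 in a fit of the 6 libraries compared and at 2.58 on log2(FPKM + 0.1) values. Camera gave the list, with a median of 0.07, an adjusted p of 5.57e-05, but fry's directional test gave 0.1005, and camera an adjusted p = 0.369 with an estimated correlation. Of 126 cell wall loosening clusters, 11 rose and 12 fell (14 and 16 adjusted over the list alone). PME31, a pectinesterase, rose by 0.45 ± 0.08, and XTH32 had a log2 fold change of -1.02 ± 0.18. Fry's directional test gave this list an adjusted p of 0.695. Outside the list, CEL1, an endoglucanase, fell from 15.3 ± 1.52 to 7.91 ± 0.361 CPM. The lignin and phenylpropanoid list, with 105 clusters, had 3 that rose and 0 that fell, among them SNL6 (Cluster-9242.35281) at 1.28 ± 0.21, which missed the threshold on log2(FPKM + 0.1) values at 1.22.

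Each hormone list held some of the clusters that passed at 1 h, where 1021 of all 52918 clusters tested passed. Of the 18039 tested clusters with a gene ontology process, 306 rose and 194 fell. The ethylene list of 113 clusters had 7 that rose and 2 that fell (20 and 3 adjusted over the list alone), with a camera adjusted p of 0.000246, and an adjusted p = 0.369 with an estimated correlation. ACS1, an enzyme that makes the ethylene precursor, rose by 1.09 ± 0.21 and lost its call at 0.79 without replicate 1 of the bent stems. Of 32 gibberellin clusters, 3 rose and 2 fell (5 and 3 adjusted over the list alone). GASA14 and SN1, small peptides of the gibberellin-regulated family, rose by 1.40 ± 0.20 and 0.86 ± 0.15, while GAI, a DELLA repressor of gibberellin responses, and GID1A, a gibberellin receptor, had log2 fold changes of -0.41 ± 0.07 and -0.56 ± 0.10. In the auxin list of 120 clusters, 3 rose and 3 fell (7 and 17 adjusted over the list alone), and ARF18, an auxin response factor, rose by 0.75 ± 0.12. Of 36 jasmonate clusters, 0 rose and 2 fell, both of them matches of the jasmonate regulator MYC2. Of these, Cluster-9242.55225 had a log2 fold change of -0.51 ± 0.10 and Cluster-9242.60773 one of -0.42 ± 0.09, whose call was lost at -0.32 without replicate 1 of the bent stems. The abscisic acid and drought list of 32 clusters had 3 that rose and 1 that fell (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.0275, and an adjusted p = 0.664 with an estimated correlation. The cluster that fell was NCED1, an enzyme of abscisic acid synthesis, at -0.69 ± 0.13.

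Among 180 early response transcription factor clusters, 6 rose and 8 fell at 1 h (15 and 13 adjusted over the list alone). DREB1D, of the cold and drought response family, had the largest rise of the genes that met the naming rule, from 2.64 ± 0.726 to 35.0 ± 41.8 CPM, and lost its call at a log2 fold change of 2.04 without replicate 1 of the bent stems, at 3.53 without replicate 1 of the unbent stems, at 3.74 in DESeq2 and at 3.69 in a fit of the 6 libraries compared. Of 121 reactive oxygen clusters, 4 rose and 0 fell (5 and 1 adjusted over the list alone). Of 63 circadian clock clusters, 1 rose and 2 fell (3 and 5 adjusted over the list alone), and the one that rose was LHY, a morning gene of the clock, at 0.36 ± 0.07, which did not pass on the FPKM values at 0.30. Among 58 photosynthesis clusters, 0 rose and 3 fell (3 and 8 adjusted over the list alone), with CAB1B, a light-harvesting protein, at -0.67 ± 0.07. Camera's adjusted p for this list was 0.0131, and the adjusted p = 0.846 with an estimated correlation. The heat shock list of 62 clusters had no member that passed, with a camera adjusted p of 0.0121 and an adjusted p = 0.737 with an estimated correlation. In the lists of other cell types, 0 of 34 xylem markers rose and 1 fell, 0 of 16 phloem markers and 0 of 66 meristem and cell cycle clusters passed, and 2 of 35 epidermis clusters rose, which were KCS1 and KCS11.

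Plastid- and mitochondrion-encoded clusters had a median log2 fold change of 0.63 at 1 h over 162 members, 77.2% of which were above 0, and 2 members passed, both higher. Camera gave an adjusted p of 0.000121, the adjusted p = 0.737 with an estimated correlation, and fry's directional adjusted p was 0.574. The bent libraries held 0.145% ± 0.0236 of their counts in these clusters against 0.120% ± 0.00290 in unbent ones, beside the rRNA shares of 4.70% and 2.97%. None of the 53 ribosomal RNA clusters passed; their median was 0.53, their mean -0.08 and fry's direction was up, with an adjusted p of 0.839. No cluster of the ringspot virus, thrips and human match lists passed at 1 h over all clusters tested, while 3 of 31 human matches were higher when adjusted over the list alone (camera adjusted p of 0.000880, and an adjusted p = 0.817 with an estimated correlation).

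**Figure D1:**
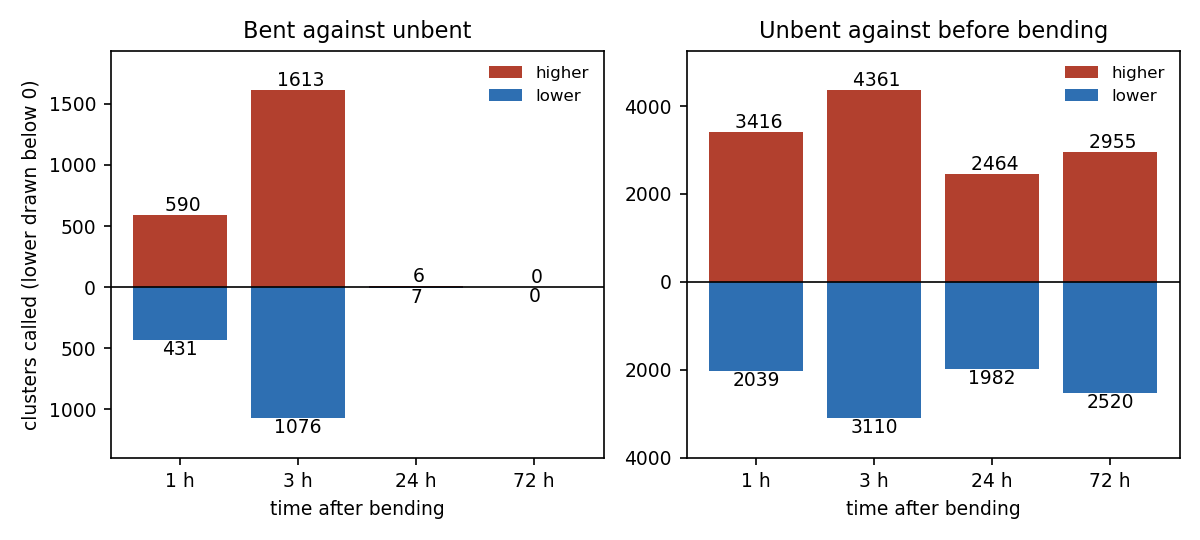
Number of clusters with an edgeR adjusted p under 0.05, higher and lower, in bent against unbent stems and in unbent stems against stems collected before bending, at 1, 3, 24 and 72 h. Bent stems differed from unbent stems in 1021 clusters at 1 h, 2689 at 3 h, 13 at 24 h and 0 at 72 h, and unbent stems differed from those collected before bending in 4446 to 7471 clusters.

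At 3 h after bending, more genes had moved, with genes of sugar metabolism, gibberellin and the clock among those that rose. TPPG, which forms trehalose from its phosphate, rose from 11 ± 3.06 to 75.8 ± 27.8 CPM (mean ± SD, n = 3 per group), a log2 fold change of 2.79 ± 0.36 (SE). The transcription factor WRKY15 rose from 52.0 ± 6.34 to 114 ± 16.5 CPM, with the smallest adjusted p of the genes named at this time, 2.27e-12 in edgeR. GASA14 rose from 8.58 ± 1.42 to 24.6 ± 2.20 CPM, SN1 from 14.2 ± 1.76 to 32.8 ± 3.02 CPM, and GA20OX2, an enzyme of gibberellin synthesis, from 11.8 ± 1.98 to 26.8 ± 2.51 CPM. Large rises were also measured for STR15, a rhodanese-like protein (2.55 ± 0.28), the chaperone ATJ11 (2.59 ± 0.30), and MIOX4, an inositol oxygenase (2.40 ± 0.34). Among the genes that fell were EXPA8, from 67.5 ± 8.36 to 27.5 ± 3.37 CPM, CSE, an enzyme of lignin synthesis, from 15.1 ± 3.40 to 6.79 ± 0.744 CPM, and YUC10, an enzyme of auxin synthesis, from 10.1 ± 1.79 to 4.58 ± 0.290 CPM.

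The same edgeR test called 2689 clusters at 3 h, 1613 higher and 1076 lower in bent stems, of which 335 and 215 changed by at least 2-fold. Of the 2689, 1985 had a Swiss-Prot name. The count fell to 1286 without replicate 1 of the bent stems and to 1251 without replicate 3 of the unbent stems.

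Of 32 gibberellin clusters, 8 rose and 1 fell at 3 h (12 and 2 adjusted over the list alone), among them GAI1, a DELLA protein, at 0.49 ± 0.06. Fry's directional adjusted p was 2.91e-05 and camera's 8.06e-05, and this call held with an adjusted p = 0.0301 with an estimated correlation. The ethylene list had 17 of 113 clusters that rose and 3 that fell (31 and 6 adjusted over the list alone), with a fry adjusted p of 0.00481 and a camera adjusted p of 6.25e-07, but an adjusted p = 0.184 with an estimated correlation. ABR1, an ethylene response family factor, rose by 1.29 ± 0.22. In the circadian clock list, 14 of 63 rose and 3 fell (15 and 4 adjusted over the list alone), including COL2 at 0.88 ± 0.12, RVE1 (Cluster-9242.41877) at 0.78 ± 0.12 and LHY at 0.40 ± 0.08. The fry adjusted p of this list was 0.00109 and the camera adjusted p 0.00172, with an adjusted p = 0.170 with an estimated correlation. In the photosynthesis list, 0 of 58 rose and 12 fell (0 and 18 adjusted over the list alone). PSBR and CAB21 (Cluster-9242.52917), of photosystem II and its antenna, had log2 fold changes of -0.64 ± 0.09 and -0.34 ± 0.07. Camera's adjusted p for this list was 3.04e-10, and the adjusted p = 0.651 with an estimated correlation.

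Other lists at 3 h held members that moved both ways. In the calcium and touch list, 14 of 109 rose and 2 fell (20 and 3 adjusted over the list alone), and the kinase CIPK12 rose from 8.33 ± 0.938 to 22.1 ± 1.99 CPM. In the cell wall loosening list, 21 of 126 rose and 14 fell (26 and 21 adjusted over the list alone). EXPB3 and the pectinesterase PME6 had log2 fold changes of -0.67 ± 0.10 and -1.63 ± 0.25, and PME31 rose by 0.45 ± 0.08. The lignin and phenylpropanoid list of 105 had 3 that rose and 3 that fell, and PAL, the first enzyme of the pathway, had a log2 fold change of -1.12 ± 0.25, a call that was lost at -0.91 without replicate 1 of the bent stems. Of 36 jasmonate clusters, 3 rose and 5 fell (3 and 8 adjusted over the list alone). LOX2.1, a lipoxygenase of jasmonate synthesis, had a log2 fold change of -0.51 ± 0.11, and MYC2 (Cluster-9242.60773) rose by 0.40 ± 0.09, a call that was lost at 0.32 without replicate 3 of the unbent stems and on the FPKM values at 0.38. Of 120 auxin clusters, 11 rose and 8 fell (17 and 15 adjusted over the list alone), with AUX22C at 0.67 ± 0.10 and SAUR50 at -0.91 ± 0.18. In the abscisic acid and drought list, 6 of 32 rose and 1 fell (6 and 2 adjusted over the list alone). Of 180 early response transcription factors, 16 rose and 8 fell (27 and 14 adjusted over the list alone), with DREB3 (Cluster-9242.3204) at 1.38 ± 0.19. The reactive oxygen list had 8 of 121 that rose and 5 that fell (9 and 6 adjusted over the list alone).

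For the heat shock list at 3 h, 4 of 62 rose and 1 fell, with a camera adjusted p of 0.0274 and an adjusted p = 0.737 with an estimated correlation. Of the markers of other cell types, 1 of 34 xylem clusters rose and 0 fell, 2 of 16 phloem clusters rose and 0 fell, 1 of 66 meristem and cell cycle clusters rose and 4 fell, and 2 of 35 epidermis clusters rose and 3 fell. The plastid- and mitochondrion-encoded list had a median of 0.37, with 2 of 162 that rose and 0 that fell, beside rRNA shares of 4.21% in bent and 3.42% in unbent stems. Of the 53 rRNA clusters, 1 rose and 1 fell. The ringspot virus list had a median log2 fold change of -0.76 over 30 clusters, none of which passed, with a camera adjusted p of 5.57e-05 and an adjusted p = 0.684 with an estimated correlation. None of the 35 thrips and 31 human match clusters passed.

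**Figure D2:**
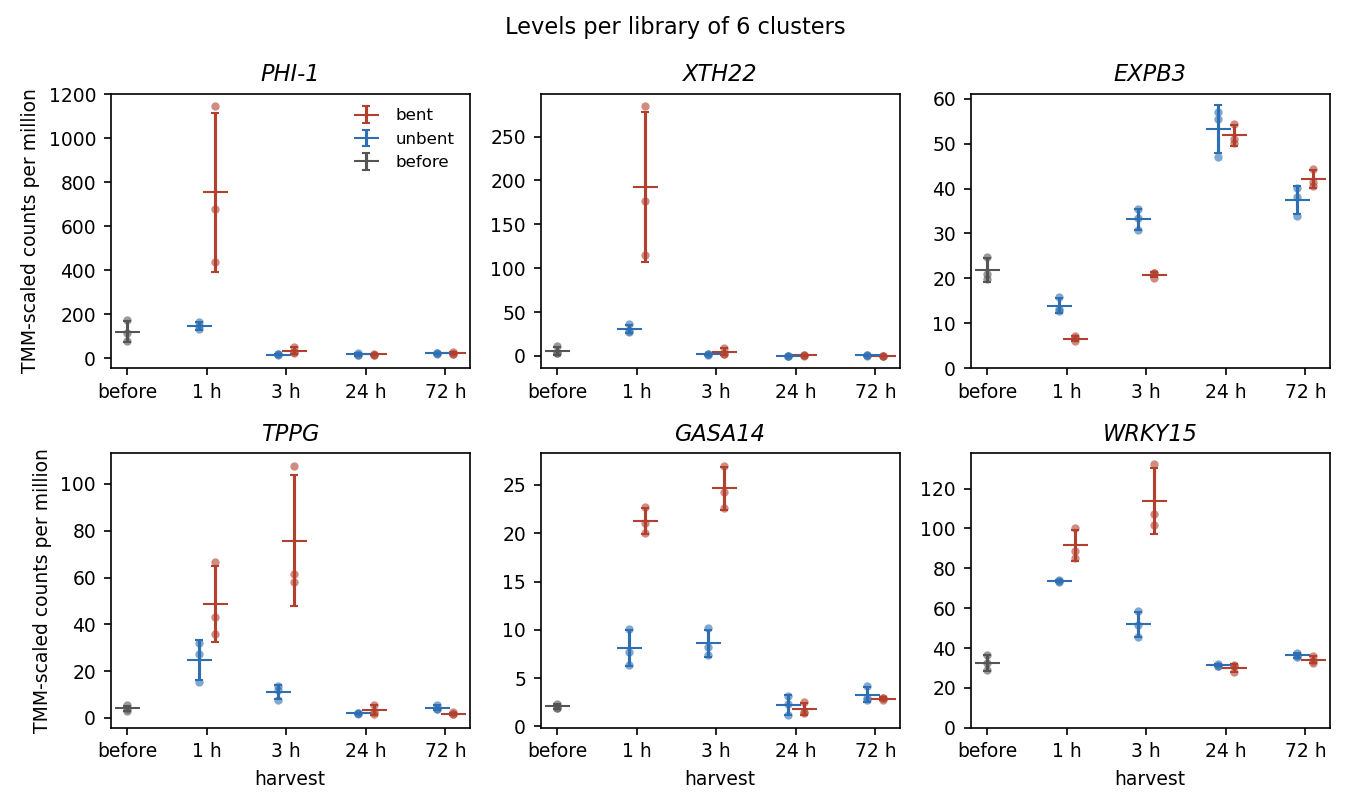
TMM-scaled CPM of 6 clusters in each library before bending and in bent and unbent stems at 1, 3, 24 and 72 h, with points for the 3 libraries of a group, a dash at the group mean and bars of 1 SD. PHI-1 and XTH22 stood highest in bent stems at 1 h, TPPG and WRKY15 stood above the unbent stems at 3 h, and GASA14 was above and EXPB3 below the unbent stems at 1 and 3 h.

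The responses of 1 h and 3 h shared genes. Of the clusters higher at 1 h, 216 were also higher at 3 h, where independent lists would share 18, and of those lower at 1 h, 95 were also lower at 3 h, against 8.76. Opposite calls were made for 4 clusters that went from higher to lower and 17 that went from lower to higher, against 12.0 and 13.1 for independent lists. The 590 clusters higher at 1 h had a median log2 fold change of 0.37 at 3 h, with 88.0% above 0 (fry adjusted p of 0.00172, and an adjusted p = 0.0342 with an estimated correlation), and the 431 lower at 1 h had a median of -0.17, with 29.2% above 0 (fry adjusted p of 0.00127, and an adjusted p = 0.0266 with an estimated correlation). Without replicates 2 or 3 of all groups, fry's calls at 3 h held for both sets, at medians of 0.41 and -0.17, and those with an estimated correlation were lost. Without replicates 2 the latter gave an adjusted p = 0.102 for either set, and without replicates 3 they gave 0.114 for the higher and 0.0551 for the lower set, against 0.0165 and 0.00678 without replicates 1. In the higher set limited to changes of at least 2-fold, the median at 3 h was 0.55 and did not pass fry's test. At 24 h, the clusters higher at 1 h had a median of 0.02 (fry adjusted p of 0.883), while those lower at 1 h had a median of -0.09 (fry adjusted p of 0.0181, and an adjusted p = 0.0342 with an estimated correlation). This last call was lost without replicates 2 of all groups, at -0.09, without replicates 3, at -0.07, and in the set of at least 2-fold, at -0.20. At 72 h the medians were 0.02 and -0.02, with a fry adjusted p of 0.883 for both.

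In edgeR's F test of whether the bending effect differs between times, 1116 clusters passed over the 4 times. The count was 1922 in DESeq2, 2012 without a filter on low counts, and 661, 320 and 545 without replicates 1, 2 and 3 of all groups. WRKY15 (adjusted p of 5.88e-09), EXPB3 (1.67e-07), MYB73 (Cluster-9242.29886, 2.53e-06), GASA14 (5.89e-05) and GA20OX2 (0.000153) were among them. Between 1 h and 3 h alone, fry's test of the difference was directional for the auxin list (adjusted p of 0.0140), the circadian clock list (0.0150) and the gibberellin list (0.0392), each of them higher at 3 h than at 1 h. With an estimated correlation, the adjusted p = 0.123 for auxin, 0.123 for the clock and 0.128 for gibberellin.

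At 24 h after bending, 13 clusters passed, 6 higher and 7 lower in bent stems, none of them by 2-fold. The 5 higher ones with a name were a pair of defensin-like proteins, small antimicrobial peptides (Cluster-9242.47675 at a log2 fold change of 0.98 ± 0.16 and Cluster-9242.53815 at 0.89 ± 0.15), the cytochrome P450 CYP714A1 (0.80 ± 0.16), and the glycosyltransferases UGT92A1 (0.61 ± 0.11) and UGT74F1 (0.46 ± 0.08). The 6 lower ones with a name were an invertase inhibitor (-0.89 ± 0.18), the asparaginase At3g16150 (-0.74 ± 0.10), the transcription factor MYB308 (-0.64 ± 0.13), PPCK1, a kinase of phosphoenolpyruvate carboxylase (-0.52 ± 0.08), the RNA-binding protein ECT2 (-0.32 ± 0.06) and COL4 (-0.31 ± 0.06). At3g16150 fell from 128 ± 16.1 to 76.8 ± 4.53 CPM and had the smallest adjusted p of these genes in edgeR, 0.00189. Among the lists, only MYB308 in the early response transcription factors and COL4 in the clock list passed over all clusters tested. Adjusted over the list alone, 9 of 62 heat shock clusters were higher and 0 lower, with a camera adjusted p of 8.40e-09, but an adjusted p = 0.248 with an estimated correlation. The auxin list had 0 clusters that passed by itself and a median of -0.09, with a fry adjusted p of 0.00481 and an adjusted p = 0.0201 with an estimated correlation. In the gibberellin list, 4 of 32 were higher and 1 lower when adjusted over the list alone. Its median was -0.09, its mean 0.14 and fry's direction was up, with an adjusted p of 0.926. The 31 human match clusters had a median of 2.27, with 5 higher when adjusted over the list alone (camera adjusted p of 1.66e-17, and an adjusted p = 0.369 with an estimated correlation), beside 0.00684% ± 0.00442 of the counts in bent and 0.00189% ± 0.000951 in unbent stems.

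The count at 24 h depended on the libraries and the tool. Without replicates 1, 2 and 3 of the bent stems it was 45, 9 and 5, and without replicates 1, 2 and 3 of the unbent stems it was 0, 10 and 5, so each of the 11 named genes lost its call in at least 1 of these fits. On the FPKM values, none of the 11 passed. On log2(FPKM + 0.1) values their fold changes were 0.98, 0.89, 0.82, 0.63 and 0.49 for the higher and -0.86, -0.70, -0.62, -0.50, -0.30 and -0.29 for the lower ones, in the order given above. DESeq2 called 60 clusters, a fit of only the 6 libraries compared 82, a fit without a filter on low counts 132 and one with a stricter filter 8, while limma-voom called 17. The directions at 24 h also varied, from 46.2% higher in the fit above to 35.4% in the fit of 6 libraries (29 higher and 53 lower), 54.5% with RLE size factors, and 53.3% without clusters of other organisms and rRNA. It was 66.7% without the 2 libraries rich in thrips matches, and likewise without replicate 2 of the bent stems, and 20% without replicate 3 of the unbent stems.

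No cluster passed at 72 h in edgeR's test, with 2883 clusters at an unadjusted p under 0.05. Limma-voom called 0 clusters, DESeq2 9, a fit of only the 6 libraries compared 14 and a fit without a filter on low counts 47, and 6 passed without replicate 1 of the unbent stems. The meristem and cell cycle list, which holds cyclins and histones H3 and H4, had a median log2 fold change of -0.18 over 66 clusters, 22.7% of them above 0. Of these, 0 were higher and 4 lower when adjusted over the list alone, with a fry adjusted p of 0.0333 and a camera adjusted p of 4.46e-10, but an adjusted p = 0.0541 with an estimated correlation. Thrips matches had a median of 1.70 (camera adjusted p of 0.00149, and an adjusted p = 0.817 with an estimated correlation), and photosynthesis clusters one of -0.06 (camera adjusted p of 5.57e-05, and an adjusted p = 0.737 with an estimated correlation). The human match list had a median of -2.38, with 1 cluster lower when adjusted over the list alone, and the ringspot virus list a median of -0.66, with camera adjusted p of 3.62e-09 and 6.91e-07 and an adjusted p = 0.694 and 0.531 with an estimated correlation.

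Unbent stems were compared with those collected before bending to show how far expression moved without bending. Such changes can follow the time of day and the days of the experiment. A disturbance of all plants on the morning of bending cannot be told apart from the time of day. The genes named for these comparisons were chosen after their values were seen. At 1 h, 14 of 36 jasmonate clusters were higher and 0 lower in unbent stems (16 and 0 adjusted over the list alone; camera adjusted p of 4.55e-14, and an adjusted p = 0.0185 with an estimated correlation). TIFY9, a repressor of jasmonate responses, rose from 2.54 ± 0.244 to 94.5 ± 9.16 CPM (mean ± SD, n = 3 per group), and AOC, an enzyme of jasmonate synthesis, from 150 ± 5.82 to 252 ± 9.21 CPM. In the calcium and touch list, 34 of 109 rose and 4 fell (39 and 11 adjusted over the list alone; camera adjusted p of 5.79e-06, and an adjusted p = 0.188 with an estimated correlation), among them CPK28, a calcium-dependent kinase, at 1.54 ± 0.09. NCED1 rose by 1.72 ± 0.14, and RAP2-4 fell from 145 ± 7.59 to 62.1 ± 2.54 CPM. Of 63 clock clusters, 11 rose and 20 fell (12 and 23 adjusted over the list alone; camera adjusted p of 0.0195, and an adjusted p = 0.276 with an estimated correlation). CAB1B had a log2 fold change of -0.74 ± 0.07, and 0 of 58 photosynthesis clusters rose while 13 fell (2 and 17 adjusted over the list alone; camera adjusted p of 5.79e-06, and an adjusted p = 0.747 with an estimated correlation). Of the organelle-encoded clusters, 4 rose and 12 fell, beside rRNA shares of 2.97% at 1 h and 5.32% before bending.

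At 3 h, unbent stems differed from those before bending in genes of the clock and of auxin. RVE8, a clock gene, fell from 51.9 ± 1.22 to 14.9 ± 1.88 CPM, and GI, an evening gene of the clock, rose from 106 ± 6.15 to 226 ± 19.3 CPM. In the clock list, 27 of 63 rose and 19 fell (29 and 19 adjusted over the list alone; camera adjusted p of 0.00566, and an adjusted p = 0.166 with an estimated correlation). Of 120 auxin clusters, 30 rose and 10 fell (34 and 13 adjusted over the list alone; camera adjusted p of 0.00639, and an adjusted p = 0.0154 with an estimated correlation), with AUX22B at 1.01 ± 0.13 and IAA13 at 0.82 ± 0.11. LTI65, a drought and cold response gene, rose from 15.4 ± 2.45 to 324 ± 114 CPM, and a MYC2 cluster, Cluster-9242.54106, fell from 81.0 ± 16.8 to 11.4 ± 0.403 CPM. GASA14 and GA20OX2, which were higher in bent than in unbent stems at this time, were also higher in unbent stems than before bending, by 2.06 ± 0.23 and 1.27 ± 0.18.

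At 24 h, 31 of 58 photosynthesis clusters rose and 0 fell in unbent stems against before bending (37 and 0 adjusted over the list alone; camera adjusted p of 8.25e-24, and an adjusted p = 0.166 with an estimated correlation), with CAB1B at 0.67 ± 0.07. Of 62 heat shock clusters, 1 rose and 18 fell (2 and 21 adjusted over the list alone; camera adjusted p of 1.59e-05, and an adjusted p = 0.392 with an estimated correlation). The ethylene list had 3 of 113 that rose and 24 that fell (4 and 29 adjusted over the list alone; camera adjusted p of 8.35e-06, and an adjusted p = 0.188 with an estimated correlation), with ERF5 (Cluster-9242.38271) falling from 72.1 ± 19.1 to 16.7 ± 1.36 CPM. At 72 h, 27 of 66 meristem and cell cycle clusters rose and 1 fell (35 and 1 adjusted over the list alone; camera adjusted p of 4.55e-14, and an adjusted p = 0.0174 with an estimated correlation). A histone H4 cluster (At1g07660) rose from 104 ± 5.91 to 156 ± 22.8 CPM. The stress response factor ZAT10 (Cluster-9242.61613) fell from 85.1 ± 21.2 to 6.92 ± 1.2 CPM. Of 31 human match clusters, 4 were higher at 72 h (11 adjusted over the list alone; camera adjusted p of 8.58e-05, and an adjusted p = 0.840 with an estimated correlation), and their share of the counts was 0.00769% ± 0.00889 at 72 h and 0.00214% ± 0.00145 before bending.

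In edgeR's test, unbent stems differed from those collected before bending in 5455 clusters at 1 h, 3416 higher and 2039 lower. The numbers were 7471 at 3 h (4361 higher and 3110 lower), 4446 at 24 h (2464 and 1982) and 5475 at 72 h (2955 and 2520). At least 2-fold changes were fewer, with 2124, 1868, 772 and 1154 clusters, and from 3 h on more of them were lower. They were 1485 higher and 639 lower at 1 h, 874 and 994 at 3 h, 232 and 540 at 24 h, and 222 and 932 at 72 h, or 19.2% higher at 72 h against 54.0% without a minimum fold. The share higher also fell under 50% without a filter on low counts, to 48.0% at 24 h and 49.1% at 72 h, with upper quartile scaling, to 45.2% at 72 h, and without replicate 2 before bending, to 49.8% at 24 h. The count at 24 h was 2959 without replicate 1 before bending, and 2920 and 2690 without replicates 1 and 3 of the unbent stems, and the count at 72 h was 3371 without replicate 1 of the unbent stems. Over all 5 time points of untreated stems, 15261 clusters changed in an F test, and 10156 without replicate 1 of every group. The genes that unbent stems changed by 3 h were followed under bending at the other times. The 4361 clusters higher and the 3110 lower in unbent stems at 3 h than before bending had median log2 fold changes, bent against unbent, of 0.01 and 0.02 at 1 h, -0.00 and 0.01 at 24 h, and 0.02 and -0.03 at 72 h. Fry's adjusted p was 0.617 to 0.942 over these 6 tests. When the lower set was limited to changes of at least 2-fold, its median at 1 h was 0.12 and passed fry's test, with an adjusted p = 0.0742 with an estimated correlation.

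**Figure D3:**
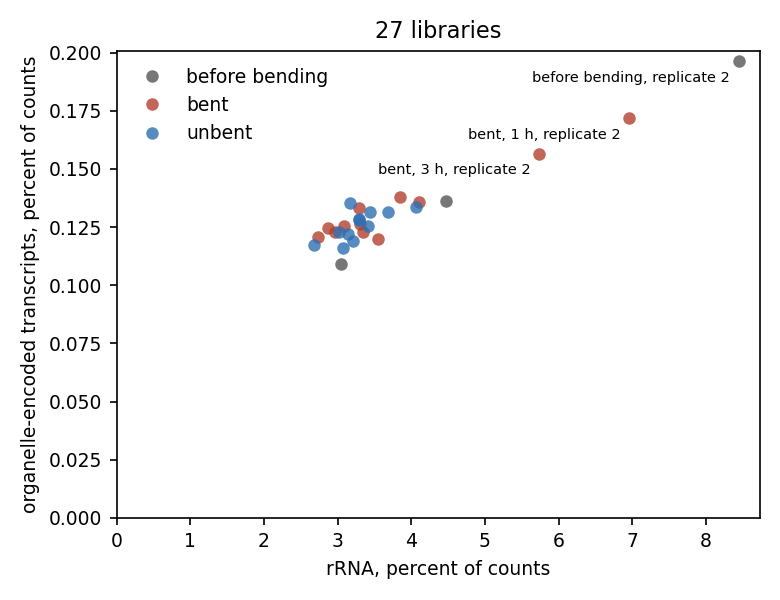
Percent of counts in rRNA clusters (horizontal axis) against percent of counts in plastid- and mitochondrion-encoded clusters (vertical axis) in each of the 27 libraries. The 3 libraries with the highest rRNA share, replicates 2 before bending, bent at 1 h and bent at 3 h, also stood highest in the organelle-encoded clusters.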

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

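The test of whether the bending effect differed between times was chosen before the data were examined, as were the splits of the samples. The tests of a steady trend, and of a disturbance of all plants, were chosen after the result was seen.

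The 1116 clusters whose bending effect differed between the 4 times stand out because the difference itself was tested, in edgeR's F test. Only genes named in the report, some of them only in this paragraph, that passed this test are listed, and XTH22 is not among them. Among wall genes named in the report, the adjusted p of this test was 1.67e-07 for EXPB3, 0.000738 for PME31, 0.00126 for EXPB16, 0.00669 for XTH23, 0.0106 for CEL1, 0.0166 for EXPA8, 0.0197 for XTH32, 0.0245 for PHI-1, 0.0246 for PME6 and 0.0317 for EXPA4. Among hormone genes it was 5.89e-05 for GASA14, 9.54e-05 for AUX22C, 0.000153 for GA20OX2, 0.000341 for MYC2 (Cluster-9242.60773), 0.000350 for GAI1, 0.00338 for YUC10, 0.00527 for SN1, 0.00627 for GID1A, 0.00661 for CYP94C1 (Cluster-9242.44453), 0.00764 for ABR1, 0.0143 for ARF18, 0.0251 for RAP2-4 and 0.0478 for ACS1. Among transcription factors and clock genes it was 5.88e-09 for WRKY15, 2.53e-06 for MYB73, 7.26e-05 for COL4, 0.000190 for MYB48, 0.00273 for COL2 and 0.0272 for RVE1 (Cluster-9242.41877). Calcium signalling genes had 3.05e-05 for CIPK12, 0.00338 for CPK13, 0.0125 for CIPK7 and 0.0266 for CML48. Genes of lipids, lignin and photosynthesis had 0.000203 for KCS1, 0.00290 for KCS11 (Cluster-9242.82290), 0.000429 for CSE, 0.00759 for SNL6, 0.000457 for CAB1B and 0.0288 for PSBR. Other genes had 8.77e-07 for PPCK1, 3.05e-05 for STR15, 0.000785 for UGT92A1, 0.00125 for ATJ11, 0.00154 for FLZ10, 0.00233 for MIOX4, 0.00514 for TPPG, 0.00789 for UGT74F1, 0.0139 for At3g16150 and 0.0341 for PHT1-7. FLZ10, CML48, CPK13, PHT1-7 and CYP94C1 are named only in this paragraph, and RAP2-4 elsewhere only for unbent stems. In fits of the 6 libraries compared, the bending call of CML48 at 1 h was lost, at a log2 fold change of 1.00. So were those of CPK13 and PHT1-7 at 3 h, at 0.61 and -1.65. Without replicate 1 of the bent stems, CML48 and RAP2-4 lost their calls at 1 h, at 0.59 and -0.24.

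Between 1 h and 3 h, fry's test of a different effect passed for the gibberellin (fry adjusted p of 0.0392), auxin (0.0140) and circadian clock (0.0150) lists, but not with an estimated correlation (adjusted p of 0.128, 0.123 and 0.123). In 30 assignments of the libraries, the real one included, 1 gave as many clusters for the effect that differs between times. It was the real one, with 1116 against at most 402 in the others. For the time course of untreated stems it was also only the real one, with 15261 against at most 2501. This argues against a chance order of the untreated libraries, though 1 in 30 is the smallest share that could be reached. For the bending effect, bent and unbent labels were shuffled within each time, which removes the effect at every time. Those assignments argue against chance labels, but cannot decide whether an effect present at all times differed between them.

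For comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05. Fitted to the 6 libraries alone with all 52918 clusters kept, rather than filtered anew as in the results, the real split and the highest other gave 933 and 2 clusters for bent against unbent stems at 1 h, 2333 and 0 at 3 h, 81 and 54 at 24 h, and 14 and 7 at 72 h. For unbent stems against before bending they gave 5680 and 0 at 1 h, 6619 and 0 at 3 h, 3955 and 4 at 24 h, and 4278 and 1 at 72 h. In each of these, 1 of 10 splits was as large. The median of the clusters higher at 1 h was 0.37 at 3 h (highest other 0.25, 1 split as large), 0.03 at 24 h (-0.04, 3 splits) and 0.02 at 72 h (0.05, 5 splits). For those lower at 1 h it was -0.17 at 3 h (-0.09, 1 split), -0.08 at 24 h (-0.06, 1 split) and -0.02 at 72 h (-0.04, 6 splits). For clusters higher in unbent stems at 3 h than before bending, the median under bending was 0.01 at 1 h (-0.04, 8 splits), 0.00 at 24 h (-0.03, 9 splits) and 0.02 at 72 h (0.04, 6 splits), and for those lower it was 0.01 (0.04, 8 splits), 0.01 (0.03, 6 splits) and -0.03 (0.04, 4 splits).

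The 1613 clusters higher in bent than in unbent stems at 3 h were already above the level before bending in unbent stems at 1 h, with a median log2 fold change of 0.42 (fry p of 4.58e-07), and the 1076 lower ones were below it, with a median of -0.25 (fry p of 2.58e-06). RNA quality of the stems taken before bending was weighed only through the rRNA share. The median of the higher clusters stayed at 0.39 without the library before bending that was richest in rRNA, which argues against that 1 library as the source. A difference in quality shared by the libraries before bending could not be seen in this way. A steady trend over the morning predicted a median under 0 for the lower clusters in unbent stems of 24 and 72 h against before bending. This holds provided that these stems were taken later in the day than the first harvest. The median was 0.11, against that prediction, but these stems also differ from the first harvest by days. A shift over the days could hide such a trend, so the test cannot decide it for the lower clusters. It stays undecided for the higher ones too, at -0.038 (fry p of 0.397). A disturbance of all plants that morning cannot be told apart from the time of day, because the calcium and touch list was higher in unbent stems at 1 h than at 24 and 72 h (median of 0.22, fry p of 2.04e-08), and the design gives no undisturbed stems at 1 h. The sources used here give the hour of bending and the hours after it, but not the clock times of the harvests. Either may be at work.

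The median of the organelle-encoded clusters in bent against unbent stems at 1 h, 0.63 (fry p of 0.163), fell to 0.22 without the 3 libraries richest in rRNA. This is what carry-over of RNA without a poly(A) tail would need. Of these 3 libraries, however, only replicate 2 of the bent stems enters the comparison at 1 h. That library also held the highest organelle-encoded share of the 1 h libraries, 0.172%, so leaving it out could lower the median whatever the cause. Carry-over therefore stays a candidate explanation that the drop does not decide. A rise of organelle transcripts under bending apart from rRNA stays open, as fry's p was 0.176 without these libraries and missed the threshold with them too. At 3 h, where replicate 2 of the bent stems was likewise the only library left out of the comparison, the median went from 0.37 to 0.06.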

How the results depend on the processing

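The fits without clusters of other organisms and rRNA, without 3 libraries rich in rRNA and without 2 libraries rich in thrips matches were chosen after the results were seen. No gene or set median that passed in either setting turned its direction under an alternative, while set medians near 0 that did not pass changed sign, and the higher and lower shares turned, as given in the results, for bent against unbent stems at 24 h and for unbent stems against before bending at 3, 24 and 72 h. Of 2348 values for 141 gene results, 2212 stayed on their side of the threshold and 136 lost it, and 100 gene results passed in each alternative counted. For bent against unbent stems these were 24 of 40 at 1 h, 29 of 42 at 3 h and 0 of 11 at 24 h. For unbent stems against before bending they were 16 of 16, 12 of 12, 10 of 10 and 9 of 10, at 1, 3, 24 and 72 h. The latter genes were chosen after their values were seen. The gene values, here and for the directions above, leave out the run without a filter on low counts and the minimum 2-fold change. The cause was not tested for any of the differences that follow, except that a minimum of 2-fold by construction leaves fewer clusters: 246 at 1 h, 550 at 3 h and 0 at 24 h for bent against unbent stems, and 2124, 1868, 772 and 1154 for unbent stems against before bending. Without a filter on low counts, 132 clusters passed at 24 h, 47 at 72 h and 2012 for the effect that differs between times, and with a stricter filter 8 passed at 24 h. DESeq2 gave 60, 9 and 1922, and fits of only the groups compared gave 82 at 24 h and 14 at 72 h. The sets limited to 2-fold gave medians of 0.55 for clusters higher at 1 h, at 3 h, -0.20 for those lower at 1 h, at 24 h, and 0.12 for those lower in unbent stems at 3 h than before, at 1 h. Of 176 list tests, camera gave 56 with an adjusted p under 0.05 at the preset correlation, 6 with an estimated correlation and 66 with the replicate block. Samples share only a replicate number. The 24 pairs with the same number had correlations of -0.03 to 0.05, none over 0.1. Of 24 samples, 14 correlated best with their own number, out of 3 candidates each, so a weak link between libraries of the same number is not excluded. The replicate block gave 1076, 2824, 21 and 0 clusters for bent against unbent stems at 1, 3, 24 and 72 h, and 1282 for the effect that differs between times. Leaving out 1 library at a time gave 370 to 1083 clusters at 1 h, 1251 to 2839 at 3 h, 0 to 45 at 24 h and 0 to 6 at 72 h, and 4122 to 4963, 5643 to 6728, 2690 to 3852 and 3371 to 4644 for unbent stems against before bending. Leaving out 1 replicate number gave 320 to 661 for the effect that differs between times and 10156 to 10991 for the time course. The medians of clusters higher at 1 h were then 0.31 to 0.41 at 3 h, 0.02 to 0.04 at 24 h and -0.00 to 0.04 at 72 h, and of those lower -0.18 to -0.17, -0.091 to -0.068 and -0.05 to 0.01. For clusters higher in unbent stems at 3 h than before they were 0.01 to 0.03 at 1 h, -0.00 to 0.02 at 24 h and -0.01 to 0.04 at 72 h, and for those lower 0.01 to 0.04, 0.00 to 0.03 and -0.04 to -0.01. Without the 3 libraries rich in rRNA, 1070 and 2131 clusters passed at 1 and 3 h, without the 2 rich in thrips matches 9 passed at 24 h, and without clusters of other organisms and rRNA 1048, 2693, 15 and 0 passed. At this depth, 58% of simulated 2-fold changes in clusters with a mean of at least 1 CPM were recovered, with 200 clusters changed in 1 comparison. The Benjamini-Hochberg threshold depends on how many clusters change, so this share can differ in the real comparisons. A cluster that did not pass is still not shown to be unchanged.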

Other observations

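The tests of gene ontology processes, and those of libraries' rRNA and thrips shares on the log2 scale, were chosen after the data had been seen. At 3 h, processes of sugar, wall and steroid metabolism passed among the clusters higher in bent stems. Fisher's exact test, 1-sided over 516 processes, gave starch and sucrose metabolism 27 of 210 clusters where 10.3 were expected (adjusted p of 0.00123), trehalose biosynthesis 9 of 35 with 1.72 expected (0.00616), galactose metabolism 10 of 47 with 2.31 expected (0.00998) and cell wall modification 7 of 30 with 1.48 expected (0.0330). The other 3 processes that passed were of steroid hormones as named in animals, each with 11 of 68 clusters and 3.34 expected (0.0330). TPPG belongs to trehalose synthesis. No process passed among clusters changed by bending at 1 h, where the smallest adjusted p was 0.200 among the higher clusters, for cellular glucan metabolism with 4 of 21, and 0.0979 among the lower, for a term named bioluminescence with 3 of 11.

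Some of the processes that passed for unbent stems against before bending follow; each time was tested separately, and no test compared the times. At 1 h, lipid metabolism (35 of 192 clusters, 17.4 expected, adjusted p of 0.0265) and phospholipid breakdown (10 of 31, 2.82 expected, 0.0407) were among the higher clusters, and protein ubiquitination (42 of 304, 16.5 expected, 1.34e-05) and response to auxin (12 of 47, 2.56 expected, 0.00145) among the lower. Microtubule-based movement was among the lower clusters at 3 h (21 of 74, 6.69 expected, 0.000752) and at 24 h (16 of 74, 4.55 expected, 0.00148). DNA recombination was among the lower clusters at 24 h (34 of 227, 14.0 expected, 0.000339) and 72 h (41 of 227, 16.6 expected, 2.86e-05), and DNA repair too (43 of 381, 23.4 expected, 0.00768, and 54 of 381, 27.8 expected, 0.000494). Clusters share sequence within a family, so these p-values take for independent what is partly not.

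Levels of the gene lists were compared across the 27 libraries, as deviations from their group means, with library shares of rRNA, virus and thrips counts, in a family of 108 relations tested by 100000 permutations within groups. None passed after Benjamini-Hochberg adjustment. The strongest was that of organelle-encoded clusters with rRNA (Pearson r of 0.94, p of 0.00131, adjusted p of 0.0794, Spearman rho of 0.76, p of 0.00369, adjusted p of 0.199), which was 0.90 and 0.69 without replicates 2 before bending and of the bent stems at 1 h. Abscisic acid and drought genes with thrips matches had an r of -0.45 (p of 0.00671, adjusted p of 0.242) and a rho of -0.54 (p of 0.00751, adjusted p of 0.203), and an r of -0.31 without replicate 2 of the bent stems at 24 h and replicate 3 before bending.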
